A study of Mus musculus with 6 samples.

How the data were processed

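RNA was measured in 6 libraries of mouse cells: 2 of wild-type J1 embryonic stem cells (ESC), 2 of neural progenitor cells (NPC) derived from that line in culture, and 2 labelled Phc1-KO. Per the labels, the stem cells were kept with LIF and serum on inactivated fibroblast feeders and separated from the feeders before use. Ribosomal RNA was removed with Ribo-Zero Gold, TruSeq libraries were made, and 50-base single-end reads were sequenced on a HiSeq2000.

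The deposited values are raw counts of reads per Ensembl mouse gene, with no normalization. The authors used STAR and HTSeq with the mm9 genome. Tool versions, annotation release and strand setting are not given in the sources used here. Each deposited table held 37620 genes and 5 closing tallies of reads given to no gene; the tallies were left out of the tests. Symbols and positions came from GENCODE M1, an mm9 annotation, which named 37205 of the genes and left 415 unnamed.

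Counts per library given to genes were 15766448 and 16018670 for ESC 1 and 2, 15226214 and 15336155 for NPC 1 and 2, and 19224273 and 21893821 for Phc1-KO 1 and 2. The reads carry no molecular identifiers, so counting intervals and floors cover counting error only. Where the libraries of a group held 0 counts of a gene, its fold was computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with a 95% counting interval.

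Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, 1 term per group) in R 4.3.3. All 6 libraries were fitted together, which left 3 residual degrees of freedom, so the spread was shared between groups. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17489 genes, and libraries were scaled by TMM. CPM are counts scaled by TMM-adjusted library size, given as mean ± SD over the 2 libraries of a group. P values were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison, with a threshold of 0.05. SE of a log2 fold change was its size divided by the square root of F.

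The 3 comparisons were NPC against ESC, Phc1-KO against ESC and Phc1-KO against NPC. The last was added because the labels of the Phc1-KO libraries conflict: the study's title and design call the cells ESC and their cell type entry reads NPC. Groups, tests, gene lists, the rule for named genes and all alternatives but 1 were set before the data were examined.

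For gene lists, 30 were written, holding 509 genes, of which 504 were in the tables, 9 under an older name, and 429 were tested. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 30 lists. The fry test was run beside them. With an estimated correlation camera uses only the 3 residual degrees of freedom, so it has little power here. Members were also counted with p adjusted over the list alone.

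Named genes were Phc1 and, per comparison, the 10 largest increases and 10 largest decreases that passed the test. These also needed both libraries of 1 group above both of the other, a mean of at least 4 CPM and a symbol that is not a numbered model. Per list they were the first 3 members as written, the 5 largest changes that passed, all that passed where there were 5 or fewer, and every Polycomb list member. Members that make up a smaller count were named after their values had been seen where the rule left them out. Results for 2 genes that met these rules are not reported here.

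The overlap of the comparisons with ESC was set beside 20 simulations. In these all 6 libraries were drawn from the ESC means and no gene was changed. Log2 fold changes of known size were tested on simulated data. In the comparison of Phc1-KO with ESC, 42% of genes with a log2 change of 1, 82% with 2 and 98% with 3 were recovered, and 10.3% of calls were false. That run used a spread per gene, equal in all groups. A second run gave all genes of a group 1 spread, that of its pair. There 6% with 1 and 86% with 2 were recovered, and 0% of calls were false. The runs differ in more than the spread between groups, so the 0% need not carry over to the data.

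Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile or total-count scaling, no filter, a filter at 1 CPM, fits of only the 2 groups compared, a test against a 2-fold change, a replicate block, each library left out in turn, and fits without mitochondrial, histone and small nuclear RNA genes. Mitochondrial genes held 0% of gene counts in every library, so leaving them out could change nothing. Counting the 2 ESC libraries as 1 was added after the data had been seen. Transcripts of Phc1 were aligned to the mm9 genome with minimap2 2.31, and figures were drawn with matplotlib 3.10.9.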

Results

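RNA levels were measured in mouse J1 embryonic stem cells (ESC), in neural progenitor cells (NPC) grown from them in culture, and in cells labelled as a knock-out of Phc1. Phc1 encodes a Polyhomeotic subunit of canonical Polycomb repressive complex 1 (PRC1), which represses developmental genes. Each group had 2 libraries, so n = 2. Between 15226214 and 21893821 reads per library were counted in genes. The labels call the 2 libraries of each group biological replicates. The ESC pair differed by a coefficient of variation beyond counting noise of 1.98%, against 28.0% for the NPC pair and 18.1% for the Phc1-KO pair. Whether the ESC libraries come from separate cultures or from 1 RNA is not known from this, so they were also counted as 1 library. In Phc1-KO 1, 1.08 reads fell outside genes for each read in a gene, against 0.661 in Phc1-KO 2, and the gene AC113316.1 took 0.910% of gene counts against 0.0792%.

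The study's title calls the Phc1-KO cells ESC, but their cell type entry reads NPC. Across genes, which are not independent replicates, Pearson's r of log CPM between Phc1-KO and ESC libraries was 0.962 to 0.963, and between Phc1-KO and NPC libraries 0.766 to 0.788. Within pairs it was 0.994 for ESC, 0.976 for NPC and 0.988 for Phc1-KO. By RNA the Phc1-KO libraries were thus closer to ESC than to NPC, which argues against the cell type entry.

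Phc1 (ENSMUSG00000040669; mm9 chromosome 6, 122267749 to 122290579, minus strand) was read first in every library. Its level was 459.7 and 460.5 CPM in ESC 1 and 2, 40.8 and 34.6 CPM in NPC 1 and 2, and 326.3 and 267.5 CPM in Phc1-KO 1 and 2. The libraries labelled Phc1-KO thus held 5529 or more counts of the gene each. The deleted part of the gene is not stated, and gene-level counts do not show which exons were read.

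**Figure D1:**
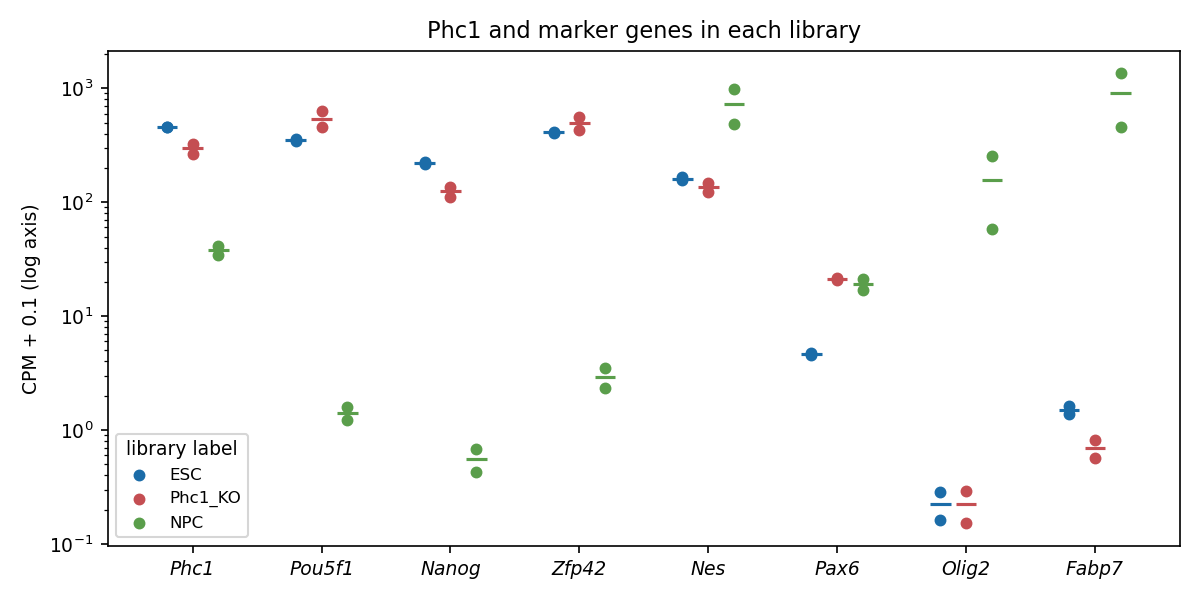
CPM plus 0.1 on a log axis for Phc1, 3 pluripotency genes and 4 neural progenitor genes. Points are libraries and short bars are means of the 2 libraries per label; Phc1 sits near 460.1 CPM in ESC, 296.9 CPM in Phc1-KO and 37.7 CPM in NPC.

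The comparison of NPC with ESC asks how RNA levels differ between a pluripotent cell and a neural progenitor made from it. Most pluripotency genes fell and most neural progenitor genes rose, many by large factors. Pou5f1, the core pluripotency factor Oct4, went from 351 ± 9.67 to 1.31 ± 0.266 CPM, a log2 fold change of -8.06 (SE 0.26). Olig2, a neural and oligodendrocyte lineage factor, went from 0.123 ± 0.0878 to 157 ± 138 CPM, a log2 fold change of 10.24 (SE 1.06). Fabp7, a fatty acid-binding protein of radial glia, rose by a log2 fold change of 9.32 (SE 0.66). By edgeR with Benjamini-Hochberg adjustment, 5315 genes were higher in NPC and 5406 lower, together 61.3% of the 17489 tested.

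Of the 26 pluripotency genes tested, 25 were lower and 1 higher, with the same counts adjusted over the list alone. Nanog changed by -8.89 (SE 0.26) on the log2 scale, Zfp42 by -7.17 (SE 0.26) and Tdgf1, a Nodal co-receptor, by -10.02 (SE 0.28). Dppa3 had no counts in NPC and was at least 365-fold lower, and Utf1 was at least 353-fold lower. The exception was Stat3, which transmits the LIF signal and rose by 0.80 (SE 0.19). The list passed camera (adjusted p = 5.72e-48) and had an adjusted p = 0.0143 with an estimated correlation.

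Neural progenitor genes were higher for 22 of 25 tested and lower for 1, or 23 and 1 adjusted over the list alone. Nes, the progenitor intermediate filament nestin, rose by 2.19 (SE 0.31) on the log2 scale, Pax6 by 2.05 (SE 0.20) and Olig1 by 8.42 (SE 0.46). Sox2, which both cell types express, fell from 349 ± 3.11 to 89.3 ± 19.7 CPM. The list passed camera (adjusted p = 1.19e-14), with an adjusted p = 0.165 with an estimated correlation.

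Astrocyte genes were higher for 6 of 10 and lower for 1, the same adjusted over the list alone. Sparcl1 rose by 9.65 (SE 0.35) and Gfap, the astrocyte filament protein, by 6.41 (SE 1.53), while Apoe fell, at -2.14 (SE 0.18). Gfap was at 3.81 CPM in NPC 1 and 112 CPM in NPC 2, and its log2 fold change was 2.49 without NPC 2; by limma-voom it did not pass (adjusted p = 0.125). Camera gave an adjusted p = 0.00166 for this list, which was 0.251 with an estimated correlation and 0.0876 or 0.0892 without Phc1-KO 1 or 2. Fibroblast genes, listed as markers of the feeder cells, were higher for 13 of 18 and lower for 2, the same adjusted over the list alone. Fap rose by 8.88 (SE 0.25), Dcn by 7.79 (SE 0.32) and Col3a1 by 6.19 (SE 0.27), whereas S100a4 changed by -2.82 (SE 0.22) and Tagln by -3.82 (SE 0.52). That list had a camera adjusted p = 2.08e-10, and adjusted p = 0.245 with an estimated correlation.

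Genes of the primitive streak and mesoderm were lower in NPC for 14 of 16 and higher for 1, Kdr, a VEGF receptor, with the same counts adjusted over the list alone. T, the streak factor Brachyury, changed by -6.18 (SE 0.43) and Eomes by -5.35 (SE 0.32). Trophoblast genes were lower for 10 of 13 and higher for 2, Tfap2a and Elf5, the same adjusted over the list alone. Germline genes were lower for 16 of 19 and higher for 1, Brdt, or 16 and 2 adjusted over the list alone. Ddx4, the germ cell helicase Vasa, changed by -5.97 (SE 0.26). The camera adjusted p was 3.15e-07, 3.15e-07 and 3.01e-06 for these lists in that order. These became adjusted p = 0.243, 0.108 and 0.165 with an estimated correlation.

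Glycolysis genes were lower in NPC for 13 of 14, cell cycle genes for 21 of 22 and Nodal pathway genes for 8 of 9, with 0 higher in each and the same counts adjusted over the list alone. Slc2a3, a glucose transporter, changed by -8.01 (SE 0.23) on the log2 scale, Hk2, hexokinase, by -4.02 (SE 0.27) and Mcm2, a replication helicase subunit, by -2.39 (SE 0.21). Lefty2, a Nodal inhibitor, changed by -9.05 (SE 0.32). By camera the adjusted p was 1.19e-14 for glycolysis, 2.91e-07 for cell cycle and 1.90e-17 for Nodal. With an estimated correlation the Nodal list had adjusted p = 0.0412, glycolysis adjusted p = 0.165 and cell cycle adjusted p = 0.356. Only the pluripotency and Nodal lists, of the 30 in this comparison, passed with an estimated correlation. The trophoblast list lost its call although its estimated correlation, -0.00893, was below the preset 0.01. A lost call therefore need not mean correlated members, since that test has only 3 residual degrees of freedom. Cell cycle and glycolysis genes did have higher estimates, 0.547 and 0.399, where the preset 0.01 can make p much too small. The fry test, which asks whether a list moves one way but not whether it does so more than other genes, passed 21, among them all 15 that camera passed.

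Interferon-response genes were lower for 12 of 16 and higher for 1, Ifit2, with the same counts adjusted over the list alone. Isg15, a ubiquitin-like interferon product, changed by -4.76 (SE 0.38). All 13 macrophage genes, a list written after the data were seen, were lower too (camera adjusted p = 4.39e-06, or 0.181 with an estimated correlation). Imprinted genes were higher for 13 of 26 and lower for 3, namely Snrpn, Impact and Phlda2, or 15 and 3 adjusted over the list alone. Igf2, a fetal growth factor, rose by 6.56 (SE 0.27) and Dlk1 by 5.46 (SE 0.49). Wnt targets were lower for 8 of 13 and higher for 4, Lgr5, Ccnd1, Nkd1 and Znrf3, or 8 and 5 adjusted over the list alone. Tested with camera, adjusted p was 0.00264, 2.85e-04 and 0.0455, and adjusted p = 0.251 for each with an estimated correlation. For the Wnt list, camera gave an adjusted p of 0.224 or 0.203 without NPC 1 or 2 and 0.148 or 0.142 without Phc1-KO 1 or 2.

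Polycomb genes differed in both directions. Of the 14 canonical PRC1 genes, 7 were higher in NPC and 2 lower, with the same counts adjusted over the list alone. Phc1 changed by -3.61 (SE 0.16) and Cbx7 by -2.59 (SE 0.31), while Cbx8 rose by 3.71 (SE 0.37), Bmi1 by 3.15 (SE 0.15), Phc2 by 2.16 (SE 0.24), Phc3 by 1.11 (SE 0.14), Cbx6 by 1.11 (SE 0.20) and Ring1 by 1.10 (SE 0.20). PRC2 genes, which encode the complex that methylates histone H3 at lysine 27, were lower for 9 of 12 and higher for 1, Phf19, the same adjusted over the list alone. Ezh2, the main methyltransferase, changed by -1.60 (SE 0.16) and Epop by -4.10 (SE 0.23). Variant PRC1 genes were higher for 4 and lower for 7 of 15, the same adjusted over the list alone. DNA methylation genes were lower for 6 of 9 and higher for 2, Dnmt3a and Tet3, the same adjusted over the list alone. The list test, camera, gave adjusted p values of 2.85e-04 for PRC2 and 1.54e-04 for DNA methylation, and adjusted p = 0.161 for both with an estimated correlation. The DNA methylation list had 0.0780 or 0.0798 without Phc1-KO 1 or 2. Camera did not pass canonical PRC1 (adjusted p = 0.138) or variant PRC1 (adjusted p = 0.406).

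Among all genes, the largest increases in NPC that met the naming rule were Neto1, Scrg1, Emcn, Slitrk1, Olig2, Grm5, Aqp4, Sparcl1, Slco1a4 and Ednrb. Neto1 was at least 332-fold higher, Scrg1 at least 162-fold and Slitrk1 at least 95.7-fold. Emcn was higher by a ratio of 2059 (95% counting interval 369 to 81366). Grm5, a glutamate receptor, rose by 9.99 (SE 0.50), Aqp4, an astrocyte water channel, by 9.71 (SE 1.88), Slco1a4 by 9.55 (SE 1.20) and Ednrb by 9.42 (SE 0.53). The NPC libraries lay far apart for Aqp4, at 15.8 and 458 CPM, and Slco1a4, at 35.0 and 206 CPM. Without NPC 2 the log2 fold changes were 5.81 for Aqp4, which did not pass by limma-voom (adjusted p = 0.103), and 7.78 for Slco1a4. The largest decreases were Rbmxl2, Dppa3, Utf1, Vrtn, Elf3, Gabrp, Plac8, Fgf4, Tcl1 and Aim1l. Rbmxl2 was at least 366-fold lower and Aim1l at least 127-fold lower, the extremes of the 9 without a count in NPC.

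No camera call was made for the remaining lists, given as higher, lower and tested, with the counts adjusted over the list alone in parentheses. They were 4, 8 and 14 for formative genes (4 and 8), 0, 3 and 6 for 2-cell-like genes (0 and 3), and 5, 3 and 15 for neuron genes (5 and 3). Oligodendrocyte genes gave 3, 1 and 8 (3 and 1), endoderm genes 4, 4 and 12 (4 and 5), and developmental transcription factors 28, 20 and 59 (28 and 20). Hox genes gave 2, 3 and 11 in cluster A (2 and 3), 4, 0 and 7 in B (4 and 0), 0, 2 and 5 in C (0 and 2), and 6, 0 and 8 in D (6 and 0). Targets of p53 gave 10, 3 and 19 (10 and 3), FGF targets 6, 2 and 12 (6 and 2), and Notch genes 3, 1 and 8 (3 and 2). Median, mean and test differed in sign for the neuron, oligodendrocyte, endoderm, Hox A and Notch lists. Against a 2-fold change, edgeR called 2629 genes higher and 2584 lower.

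The comparison of Phc1-KO with ESC asks which RNA levels differ in cells labelled as lacking a PRC1 subunit. Among the genes listed beforehand, 18 of 31 Hox genes and 7 of 18 fibroblast markers were higher. Lower were 10 of 16 primitive streak, 8 of 13 trophoblast, 9 of 16 interferon-response and 6 of 14 glycolysis genes. No list passed with an estimated correlation, a test with only 3 residual degrees of freedom. Tfpi2, an inhibitor of serine proteases, rose from 0.123 ± 0.00120 to 16.4 ± 0.857 CPM, a log2 fold change of 6.98 (SE 0.34). Emr1, the macrophage surface protein F4/80, fell to 0.226 ± 0.0229 CPM, a log2 fold change of -5.69 (SE 0.35). By edgeR with Benjamini-Hochberg adjustment 858 genes were higher and 1006 lower, together 10.7% of those tested, and 5126 had an unadjusted p under 0.05. With the ESC pair counted as 1 library, chosen after the data were seen, 62 were higher and 83 lower; without ESC 1 the counts were 46 and 66, and without ESC 2 they were 32 and 60. They were 672 and 501 without Phc1-KO 1, 81 and 57 without Phc1-KO 2, 1757 and 1958 without NPC 1, 1754 and 1947 without NPC 2, 1791 and 2108 when only these groups were fitted, 1375 and 1165 by DESeq2, 83 and 95 against a 2-fold change, and 683 and 1223 with total-count scaling.

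Phc1 itself changed by a log2 fold change of -0.63 (SE 0.15, adjusted p = 0.0412) by edgeR, from 460.1 ± 0.568 to 297 ± 41.6 CPM. It was below both ESC libraries in both Phc1-KO libraries. The call was lost without a low-count filter (adjusted p = 0.0528) and without Phc1-KO 2, ESC 1 or ESC 2 (adjusted p = 0.135, 0.316 and 0.304).

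Hox genes, which pattern the body axis and are classic Polycomb targets, were higher in Phc1-KO for 18 of 31 tested and lower for 0. All 31 had positive log2 fold changes under each of the 4 scalings tried. Cluster A had 8 of 11 higher, 11 adjusted over the list alone, cluster B 4 of 7 (5 adjusted over the list alone), cluster C 2 of 5 (4 adjusted over the list alone) and cluster D 4 of 8 (4 adjusted over the list alone). Hoxa10 went from 0.276 ± 0.0460 to 9.22 ± 2.51 CPM, a log2 fold change of 5.03 (SE 0.51), and Hoxd13 rose by 3.91 (SE 0.53), Hoxb6 by 3.29 (SE 0.55) and Hoxa5 by 3.17 (SE 0.36). From camera came an adjusted p of 1.47e-12, 1.03e-04, 0.00343 and 6.71e-05 for clusters A to D, and adjusted p = 0.251 for A and 0.317 for the others with an estimated correlation. With the ESC pair counted as 1 library, 2 Hox genes passed, both in cluster A.

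**Figure D2:**
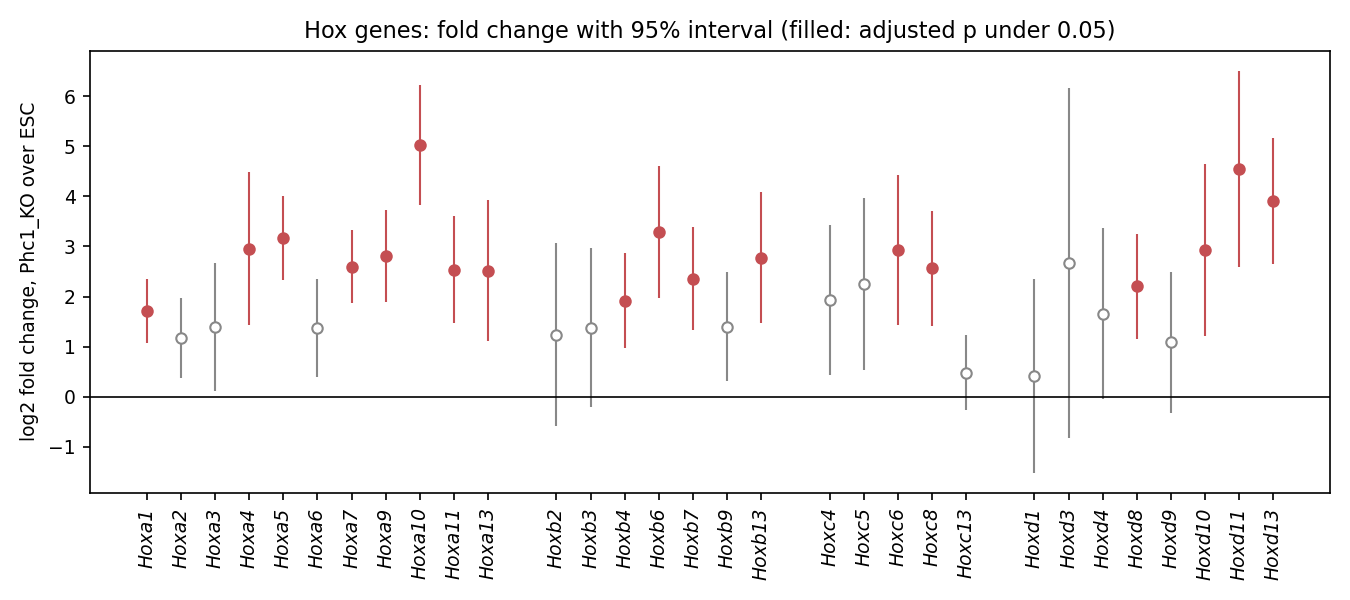
Log2 fold change of each of the 31 Hox genes tested, Phc1-KO over ESC, with bars for the 95% interval; filled points have adjusted p under 0.05. The 18 filled points and the 13 open ones all lie above 0.

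In the same libraries fibroblast genes were higher for 7 of 18 and lower for 0, or 9 and 0 adjusted over the list alone. Postn, the matrix protein periostin, went from 4.78 ± 0.213 to 183 ± 21.5 CPM, a log2 fold change of 5.26 (SE 0.55). Dcn, decorin, rose by 3.68 (SE 0.28), S100a4 by 2.98 (SE 0.20), Prrx1 by 2.35 (SE 0.53) and Lum by 1.69 (SE 0.18). The collagen genes Col1a1 (log2 fold change 0.13, 95% interval -0.75 to 1.01), Col1a2 (0.62, 95% interval -0.29 to 1.53) and Col3a1 (-0.28, 95% interval -0.79 to 0.24) did not pass. As a set by camera, adjusted p was 7.18e-10, and adjusted p = 0.261 with an estimated correlation.

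Other developmental transcription factors went both ways, with 9 of 59 higher and 6 lower, or 12 and 9 adjusted over the list alone. Wt1 rose by 2.81 (SE 0.42), while Gsc changed by -4.33 (SE 0.51), Sim2 by -3.22 (SE 0.56), Dlx3 by -3.19 (SE 0.61) and Foxd1 by -2.94 (SE 0.37). Camera did not call the list (adjusted p = 0.163). Of 25 neural progenitor genes 2 were higher, Pax6 at 2.21 (SE 0.20) and Nfib at 0.76 (SE 0.15), and 3 lower, Prom1, Notch1 and Msi1, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.847).

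Primitive streak and mesoderm genes were lower for 10 of 16 and higher for 0, or 14 lower adjusted over the list alone. T went from 57.4 ± 0.994 to 6.61 ± 0.797 CPM, a log2 fold change of -3.12 (SE 0.34). Lhx1 changed by -4.47 (SE 0.47), Gsc, an organizer factor, by -4.33 (SE 0.51), Mixl1 by -3.68 (SE 0.33) and Eomes by -1.44 (SE 0.24). Trophoblast genes were lower for 8 of 13 and higher for 0, or 9 lower adjusted over the list alone. Among them the keratin genes Krt19 changed by -3.68 (SE 0.21), Krt7 by -2.94 (SE 0.46) and Krt18 by -1.76 (SE 0.18). The camera adjusted p was 1.14e-15 and 1.56e-10, and adjusted p = 0.145 for both with an estimated correlation. Wnt targets were lower for 5 of 13 (6 adjusted over the list alone) and higher for 2, Lef1 and Notum, with the same number higher adjusted over the list alone. Sp5 changed by -3.24 (SE 0.28) and Axin2, a feedback inhibitor, by -1.79 (SE 0.26). That list had a camera adjusted p = 0.00165, 0.220 with an estimated correlation, and 0.0933 or 0.0679 without Phc1-KO 1 or 2.

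Interferon-response genes were lower for 9 of 16 and higher for 0, or 13 lower adjusted over the list alone. Isg15 went from 8.18 ± 0.396 to 0.933 ± 0.0879 CPM, a log2 fold change of -3.12 (SE 0.31), Mx2, an antiviral GTPase, changed by -4.10 (SE 0.43) and Ifit1 by -3.09 (SE 0.27). Of 13 macrophage genes, a list written after the data were seen, 7 were lower and 0 higher in the same libraries. Camera adjusted p for the interferon list was 2.39e-14, and adjusted p = 0.145 with an estimated correlation. Glycolysis genes were lower for 6 of 14 and higher for 0, or 10 lower adjusted over the list alone. Slc2a3 changed by a log2 fold change of -1.58 (SE 0.17), Tpi1, triosephosphate isomerase, changed by -1.29 (SE 0.19) and Pgk1 by -1.10 (SE 0.19). By camera the adjusted p was 3.61e-08, and adjusted p = 0.249 with an estimated correlation.

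Imprinted genes were lower for 8 of 26 (10 adjusted over the list alone) and higher for 3, Mest, Ndn and Impact (4 adjusted over the list alone). The largest decreases included the non-coding RNAs of the Dlk1-Meg3 region, with Mirg at -3.61 (SE 0.19), Rian at -2.74 (SE 0.15) and Meg3 at -2.07 (SE 0.41). H19 changed by -1.62 (SE 0.41). Tested with camera, adjusted p was 8.28e-04, 0.293 with an estimated correlation and 0.106 without Phc1-KO 2.

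Pluripotency genes went both ways: 4 of 26 were higher and 4 lower, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.772). The fry test passed the list as lower (adjusted p = 0.00987), at a median log2 fold change of -0.05. Dppa2 rose by 1.64 (SE 0.18), Gdf3 by 1.14 (SE 0.19), Nr0b1 by 0.77 (SE 0.15) and Fgf4 by 0.64 (SE 0.13). Dppa3 changed by -2.63 (SE 0.35), Tfcp2l1, a naive pluripotency factor, by -1.76 (SE 0.22), Tcl1 by -1.13 (SE 0.23) and Nanog by -0.83 (SE 0.16). Pou5f1 was at 540.0 ± 122 CPM against 351 ± 9.67 CPM (log2 fold change 0.62, 95% interval 0.20 to 1.04), which did not pass. Formative genes, expressed on exit from the naive state, were higher for 5 of 14 and lower for 0, or 6 and 0 adjusted over the list alone. Those that rose were Foxd3 at 1.85 (SE 0.29), Dnmt3a at 1.53 (SE 0.13), Sall2, Lef1 and Zic2. Of the 2-cell-like genes 3 of 6 were higher (4 adjusted over the list alone), Zscan4f by 3.29 (SE 0.51), Zscan4d by 2.46 (SE 0.44) and Usp17le by 2.26 (SE 0.50). The list test, camera, gave adjusted p values of 6.59e-05 for the formative and 0.00392 for the 2-cell-like list, and adjusted p = 0.145 and 0.317 with an estimated correlation.

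Few Polycomb genes differed besides Phc1. Canonical PRC1 genes were higher for 2 and lower for 1 of 14, the same adjusted over the list alone. Bmi1, the PCGF4 subunit, went from 9.53 ± 0.310 to 45.6 ± 2.67 CPM, a log2 fold change of 2.26 (SE 0.14), and Cbx8 rose by 1.84 (SE 0.37). The Phc1 paralogs Phc2 (log2 fold change -0.33, 95% interval -0.88 to 0.22) and Phc3 (-0.42, 95% interval -0.76 to -0.08) did not pass. In the variant PRC1 list Pcgf5 alone of 15 passed, at -1.87 (SE 0.20), and in the PRC2 list Jarid2 rose by 0.58 (SE 0.13) while Ezh1 changed by -1.19 (SE 0.25), of 12, all with the same counts adjusted over the list alone. From camera came an adjusted p of 0.429, 0.847 and 0.921 for the canonical PRC1, variant PRC1 and PRC2 lists. DNA methylation genes were higher for 1 of 9, Dnmt3a, the same adjusted over the list alone, with a camera adjusted p = 0.00918, 0.249 with an estimated correlation and 0.0962 without Phc1-KO 1.

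**Figure D3:**
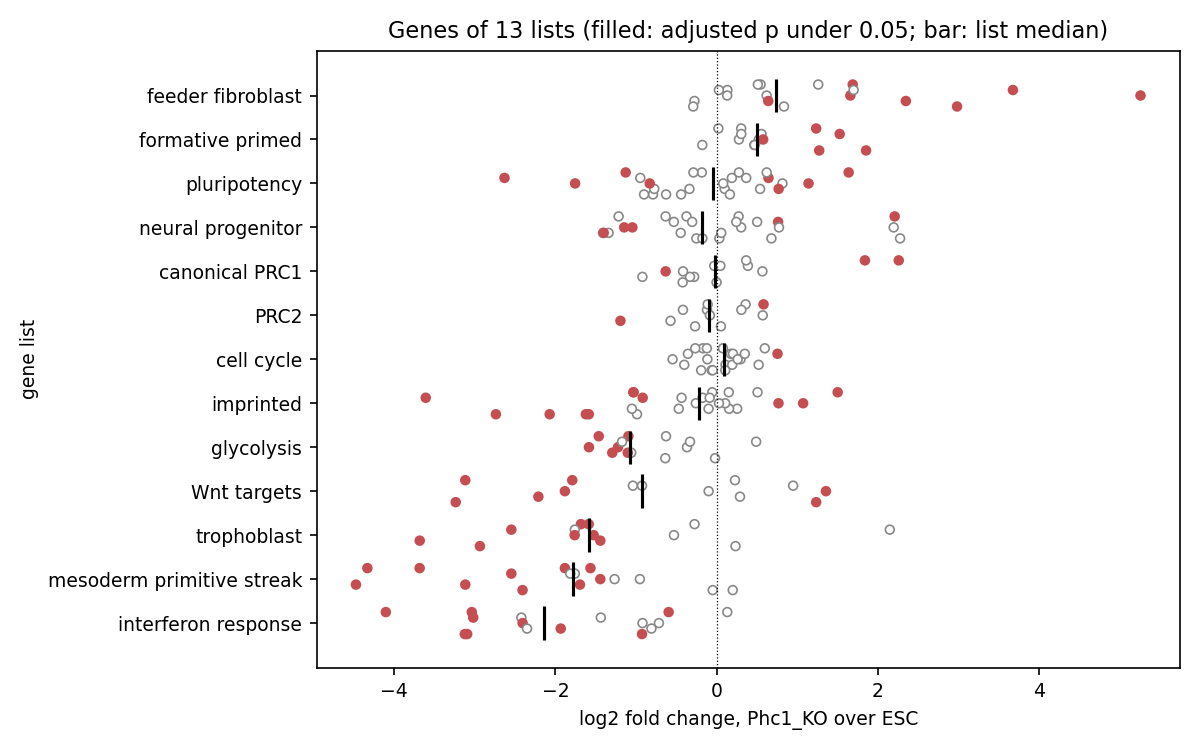
Log2 fold change, Phc1-KO over ESC, of the tested genes in 13 of the 30 lists; filled points have adjusted p under 0.05 and bars mark list medians. The interferon median was -2.14, the primitive streak median -1.79 and the fibroblast median 0.74.

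Targets of p53 and CDK inhibitors were higher for 5 of 19, Cdkn2a at 1.71 (SE 0.31), Bax, Ccng1, Plk2 and Aen, or 6 higher and 1 lower adjusted over the list alone. Endoderm genes were higher for 3 of 12, Cubn at 2.61 (SE 0.23), Col4a1 and Col4a2, the same adjusted over the list alone. Notch genes were lower for 2 of 8, Hey1 at -2.15 (SE 0.29) and Notch1 at -1.15 (SE 0.19), or 6 adjusted over the list alone. As a set by camera, adjusted p was 0.0309, 0.00918 and 7.53e-04 for these lists, and adjusted p = 0.293, 0.317 and 0.249 with an estimated correlation. Without Phc1-KO 1 camera gave 0.188 for the p53 list and 0.173 for endoderm. Of the 30 lists camera passed 17 and fry 16, and 14 passed both. Of those camera passed, endoderm, Hox C and Hox D did not pass fry (adjusted p = 0.0636, 0.0699 and 0.0699). The pluripotency and Nodal lists passed fry but not camera.

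Lists without a camera call included astrocyte genes, with 1 of 10 higher, Gja1, and 2 lower, Aldoc at -3.29 (SE 0.27) and Aldh1l1. Oligodendrocyte genes had 1 of 8 higher, Pdgfra at 2.88 (SE 0.24). Germline genes had 2 of 19 higher, Taf7l and Hormad1, the cell cycle list 1 of 22, Ccne1, and Nodal genes 2 of 9, Lefty1 at 1.61 (SE 0.18) and Gdf3. These 5 lists had the same counts adjusted over the list alone. FGF targets had 2 of 12 higher, Myc and Spry2, or 3 higher and 2 lower adjusted over the list alone. Of the 15 neuron genes 0 passed edgeR, as adjusted over the list alone, 4 had an unadjusted p under 0.05, and 1 each passed DESeq2 and limma-voom. Median, mean and test differed in sign for the neural progenitor, canonical PRC1 and variant PRC1 lists.

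The largest increases in Phc1-KO that met the naming rule were Tfpi2, Olr1, Gpr149, Ccl11, Postn, Mmp10, Hoxa10, Mmp3, Ctla2a and Itga2. Ccl11, the chemokine eotaxin, rose by 5.27 (SE 0.42), and the matrix metalloproteinase genes Mmp10 and Mmp3 by 5.03 (SE 0.30) and 4.63 (SE 0.52). The largest decreases included Emr1, Ifi44, Ccl9, Calb2, Grin1, Ndufa4l2, Pkd1l1, Trpm1 and Cyp26a1. Ifi44, an interferon-induced gene, changed by -5.25 (SE 0.55), Ndufa4l2 by -4.45 (SE 0.33) and Cyp26a1, a retinoic acid-degrading enzyme, by -3.81 (SE 0.54). Of the 117 genes called in this comparison that the naming rule picked, Phc1 aside, 21 kept their call in every fit that left out 1 library and 41 with the ESC pair counted as 1. The 21 were Bmi1, Ctla2a, Dcn, Krt19, Mirg, Mmp10, Tfpi2, Rian, Pdgfra, Ccl11, Aldoc, Pkd1l1, S100a4, Itga2, Cubn, Ndufa4l2, Ifit1, Emr1, Grin1, Trpm1 and Pax6.

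Phc1-KO was also compared with NPC because of the cell type entry. Most pluripotency genes were higher and most neural progenitor genes lower in Phc1-KO, many by large factors. Pou5f1 was at 540.0 ± 122 CPM against 1.31 ± 0.266 CPM in NPC, a log2 fold change of 8.68 (SE 0.27). Fabp7 was at 0.598 ± 0.180 CPM against 907 ± 634 CPM, a log2 fold change of -10.54 (SE 0.71). By edgeR with Benjamini-Hochberg adjustment 5641 genes were higher and 5718 lower, and 2827 and 2952 against a 2-fold change.

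In this comparison 24 of 26 pluripotency genes were higher and 1, Stat3, lower, and 1 neural progenitor gene, Sox2, was higher and 23 of 25 lower. Nodal genes were higher for 8 of 9 and lower for 1. Glycolysis genes were higher for 13 of 14 and cell cycle genes for 20 of 22, with 0 lower in each. Fibroblast genes were lower for 12 of 18 and higher for 3, S100a4, Tagln and Acta2. All these counts were the same adjusted over the list alone. The camera adjusted p was 2.80e-43 for pluripotency, 1.23e-13 for neural progenitor, 3.67e-17 for Nodal, 1.80e-08 for glycolysis, 3.34e-07 for cell cycle and 1.47e-05 for fibroblast genes. With an estimated correlation adjusted p = 0.0167, 0.154, 0.0422, 0.240, 0.432 and 0.422 in the same order. Of the 30 lists fry passed 22, among them all 15 that camera passed. Phc1 was higher in Phc1-KO by a log2 fold change of 2.98 (SE 0.16).

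Genes with the largest increases over NPC were Utf1, Rbmxl2, Vrtn, Fgf4, Spink3, Prl2c2, Gdf3, Foxd3, Dppa5a and Chrna9. Utf1 was at least 512-fold higher, Rbmxl2 at least 357-fold, and Dppa5a rose by 10.51 (SE 0.24). The largest decreases were Aqp4, Slco1a4, Scrg1, Pcdhb12, Erbb4, Fabp7, Grm5, Gria2, Inmt and Slitrk1. Scrg1 was at least 197-fold lower and Pcdhb12 at least 182-fold lower, and Grm5 changed by -10.48 (SE 0.51). The call for Aqp4 was lost by limma-voom (adjusted p = 0.109) and with either Phc1-KO library left out, and its NPC libraries were at 15.8 and 458 CPM.

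Overlap between the comparisons with ESC was counted last. Phc1-KO and NPC shared 308 genes higher and 515 lower than ESC, against 260.8 and 311.0 from the list sizes alone, while 205 were higher in NPC and lower in Phc1-KO and 283 the reverse, against 305.7 and 265.2. In 20 simulations all 6 libraries were drawn from the ESC means with no gene changed. At most 1 gene was higher in both and 0 lower in both. Almost no gene is called in such data, so they cannot show what overlap to expect between groups that differ. Pearson's r of the log2 fold changes across genes was 0.150, against a mean of 0.502 in the simulations, and their covariance 0.297 against 0.0603. Both comparisons use the same ESC libraries. Log2 ratios of CPM plus 0.5, on another scale than the fitted fold changes, were taken with 1 ESC library per comparison. Their covariance was 0.154 or 0.146 with that library shared and 0.128 or 0.129 with a separate one for each comparison. The ESC libraries differed little beyond counting noise, so this split cannot remove a deviation that both share. Genes higher and lower in both numbered 28 and 56 with the ESC pair counted as 1, 23 and 43 without ESC 1, 12 and 42 without ESC 2, 184 and 247 without Phc1-KO 1, 37 and 41 without Phc1-KO 2, 595 and 933 without NPC 1, and 609 and 939 without NPC 2.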

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

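Counting the ESC pair as 1 library was the test chosen only after the results had been seen; the other alternatives were planned. Of the genes that passed among the lists, the largest changes and Phc1, 368 in NPC against ESC, 150 in Phc1-KO against ESC and 367 in Phc1-KO against NPC, 0 turned direction under any of them. The balance of the counts for Phc1-KO against ESC, 858 higher and 1006 lower, turned to more higher in 3 of them: 1375 and 1165 by DESeq2, 672 and 501 without Phc1-KO 1, and 81 and 57 without Phc1-KO 2. In the other comparisons the 2 sides were near even and which was larger also varied. Against a 2-fold change, which asks for more than a difference from 0, the counts fell to 2629 higher and 2584 lower for NPC against ESC, 83 and 95 for Phc1-KO against ESC, 2827 and 2952 for Phc1-KO against NPC, and 30 and 66 for genes higher and lower in both comparisons with ESC. With the ESC pair counted as 1, Phc1-KO against ESC had 62 higher and 83 lower and the overlap 28 and 56; fewer libraries were then counted. Fitting only the groups compared gave 1791 and 2108, with an overlap of 574 and 956; DESeq2 gave 496 higher in both; the cause was not tested. At an adjusted p of 0.01 the overlap was 53 and 99. With 1 library left out, counts for Phc1-KO against ESC ran from 32 to 1757 higher and from 57 to 1958 lower, and the overlap from 12 to 609 and from 41 to 939. A group with 1 library left is assumed to vary like the others. The log2 fold change of Phc1 ran from -0.78 to -0.49 with 1 library left out; it no longer passed at -0.63 without a low-count filter, at -0.63 against a 2-fold change and at -0.63 with the ESC pair counted as 1 (adjusted p = 0.295 by edgeR). In the replicate block fit, which takes equal replicate numbers as paired, NPC against ESC had 5142 higher and 5282 lower and Phc1-KO against ESC 636 and 791; the deviations of equal numbers correlated at 0.0174, 0.0202 and -0.0207 across genes. Other scalings and filters kept the counts of all 3 comparisons within 1.5-fold. Genes called in NPC against ESC that the naming rule picked numbered 186, of which 166 held in every fit with 1 library left out and 170 with the ESC pair counted as 1. With 2 libraries per group, known changes were put into simulated data for Phc1-KO against ESC. With a spread per gene, equal in all groups, 42% of genes at a log2 change of 1 and 82% at 2 were recovered. With 1 spread per pair for all its genes, 6% and 86% were recovered. Changes of 1 or less are thus mostly missed. DESeq2 gave no adjusted p for 1696 genes in Phc1-KO against ESC.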

Other observations

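All tests in this part were chosen after the patterns had been seen, and those of the feeder share and of swaps within the series after the values they measure had been seen too. Both lists were written after related genes had been noticed among those lower in Phc1-KO, from members whose values had not been read. None of their genes is in the lists set earlier or among the largest changes. Macrophage genes were lower in Phc1-KO than in ESC for 7 of 13 and higher for 0, with C1qc at -4.62, C1qa at -3.34 and Ctss at -2.85 on the log2 scale, and in NPC all 13 were lower than in ESC. Hypoxia-inducible genes were lower in Phc1-KO for 6 of 12 and higher for 0, with Adm, a vasodilator peptide, at -1.72, Egln1, an oxygen-sensing hydroxylase, at -1.72 and P4ha1 at -1.58. Of their members 2 of the macrophage and 10 of the hypoxia genes stood at 10 CPM or more in ESC.

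Xist, the RNA that silences an X chromosome, was at 111 and 115 CPM in the ESC libraries, 0.855 and 0.779 CPM in NPC, and 245 and 176 CPM in Phc1-KO. Tsix lies antisense to it and the strand setting is not given, so reads of the 2 genes are not surely separated. Tsix was at 12.8 and 12.7 CPM in ESC and 26.6 and 22.9 CPM in Phc1-KO.

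Of the Hox genes 18 of 31 were higher in Phc1-KO, as were 7 of 18 fibroblast markers, though neither kind of list passed with an estimated correlation. A larger share of the same feeders would raise all fibroblast markers by 1 factor only if the stem cells made none of them. Among the 6 under 10 CPM in ESC the log2 fold changes of Postn and Twist1, the highest and lowest, differed by 5.13 (SE 0.61). This goes against 1 common factor. Twist1 was at 9.22 CPM in ESC, from feeders or from the stem cells themselves. The spread did not rest on Twist1 alone. Postn rose by 5.26 (SE 0.55) and Dcn by 3.68 (SE 0.28), against 1.70 (SE 0.45) for Thy1, 1.69 (SE 0.18) for Lum and 1.66 (SE 0.26) for Fap. The collagen genes Col1a1, Col1a2 and Col3a1 did not pass. As the stem cells may make some of these RNAs, a larger feeder share is not excluded as a part of the pattern. A fibroblast-like population of another kind may also account for part of the pattern. The log2 ratio between the Phc1-KO libraries differed by -0.21 in median between 18 Hox and 7 fibroblast genes (two-sided permutation test, p = 0.270), which excludes nothing. Loss of Polycomb repression, a possible explanation given the Phc1-KO label, was not tested and stays open. The other developmental transcription factors listed went both ways, with 9 of 59 higher and 6 lower (camera adjusted p = 0.163).

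Phc1 RNA was kept at a high level in libraries labelled as its knock-out. Against reads from a near-identical copy of Phc1 elsewhere in the genome, 13 coding transcripts of Phc1 of at least 500 bases gave 0 alignments at another locus at 90% identity over 500 bases. Nor does a swap of Phc1-KO libraries with ESC libraries of this series account for it, since the lowest ESC library held 1.41 times the Phc1 CPM of the highest Phc1-KO library. A swap with NPC libraries is argued against by 25 of 26 pluripotency genes that were higher in both Phc1-KO libraries than in both NPC libraries. A deletion that leaves most of the transcript, a wrong label or a swap with an outside sample could each give this level, and these were not tested.

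Of the interferon-response genes 9 of 16 were lower in Phc1-KO, and fewer macrophages carried over from the feeder layer may be a source. The macrophage list had a median log2 fold change of -1.82 and passed camera (adjusted p = 3.47e-08, or 0.168 with an estimated correlation), which met the prediction written for it. A further condition, that its members move alike as asked of the fibroblast markers, was added after this value had been seen. Cd53 and C1qc differed by 5.16 (SE 0.78), and the more abundant Laptm5 at -0.32 and Coro1a at -0.55 did not pass, so the explanation stays open. The labels name a feeder depletion before use, how complete is not known, and a response of the cells themselves was not tested.

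Of the glycolysis genes 6 of 14 were lower in Phc1-KO and the list did not pass with an estimated correlation (adjusted p = 0.249). A candidate explanation for these 6 is lower hypoxia-inducible transcription. The hypoxia-inducible list had a median log2 fold change of -0.73 and passed camera (adjusted p = 7.40e-08, or 0.124 with an estimated correlation), as predicted before its values were read. In NPC, where 13 of 14 glycolysis genes were lower, 2 hypoxia-inducible genes were higher and 5 lower. The list did not move as a whole there, with a median of -0.20 (camera adjusted p = 0.779). The 5 lower in NPC, Vegfa, Kdm3a, Car9, Mxi1 and Higd1a, were not among the 6 lower in Phc1-KO. Of those 6, Adm and P4ha2 were higher in NPC, at 2.60 and 0.71 on the log2 scale. Egln1, Bnip3l, P4ha1 and Plod2 did not pass there. In NPC glycolysis genes thus fell without a called fall of the hypoxia-inducible genes that fell in Phc1-KO, though other members fell. Pattern and test come from the same libraries, so the explanation remains a hypothesis.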
